A study of Rattus norvegicus with 12 samples.

How the data were processed

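The deposited values were log2 MAS5 signals made by the authors with Affymetrix Expression Console, per the submitters' processing notes, from 6 µg of total RNA per animal; the program versions are not given in the sources used here. Computed from the values, the linear signals of each array had a trimmed mean of 500 with 2% trimmed at each end, so each array had been scaled by 1 factor. The authors' deposited table also holds a p-value per probe set and comparison, whose test is not named and which an unequal-variance test on the log2 signals matched to 1.2e-05. The fold changes deposited by the authors equal 2 to the size of the difference between group means of log2 signal. The direction given as up or down in the same table, per the file headers, served only to sign those fold changes. A second deposited table held identical signals.

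Of 31099 probe sets, 20832 carried 1 gene symbol, 436 several and 9831 none. Probe sets with 1 symbol were kept, and of these the one with the highest mean signal stood for its gene. Detection calls were not given in the sources used here, so a gene was tested when its mean log2 signal was above the median of all probe sets, 6.71. This left 9485 genes over 12 arrays and 9459 over 11. The labels give a separate animal number for each array, and each array was treated as 1 animal.

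Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with moderated variances, a trend with signal and the robust option, which left 8 residual degrees of freedom over 12 arrays and 7 over 11. Every adjusted p of a gene in the text is a moderated limma p adjusted by Benjamini-Hochberg over all genes of the comparison, and a gene passed, was called or changed when it was under 0.05. The SE is the moderated standard error of limma. In total 38 lists were fixed in advance, 26 of processes and 12 of cell types, and the 32 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Their p values were adjusted over the lists of a comparison.

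Genes were named by a rule fixed before the values were seen. It took the 10 largest rises and 10 largest falls that passed with groups that did not overlap, or the smallest p where none passed, leaving out placeholder symbols, then up to 4 genes of each list with the smallest p, and a panel of 20 fatty liver genes, of which 15 were measured; some of the others were not analysed here. The fit of 11 arrays was chosen after the data were seen.

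The fits were tried on simulated signals with the spread of these arrays and 200 changed genes in each of 10 draws. Over 12 arrays 38.9% to 40.3% of changes of log2 size 1 and 74.8% to 76.4% of size 2 were found, and over 11 arrays 65.1% to 71.9% and 93.8% to 95.7%. False calls made up 3.87% to 5.28% of calls, and no call had the wrong sign. Each simulated gene had 1 pooled spread, equal on every array. The array labelled normal diet 3 widens that spread over the 12 arrays, so the rates for 12 arrays do not describe a fit in which 1 array stands apart. A shifted list of 30 genes was found in all 10 draws, and an unshifted one was called in 1 draw of 1 comparison. Simulated genes were drawn independently of each other, so these draws do not test list calls where genes of a list move together. Unchanged groups were simulated 100 times with 1 mean per gene and the spread of each gene within each group of the 11 arrays. Genes were drawn independently there too, so the ranges leave out spread from genes that move together. Figures were drawn with matplotlib 3.10.9.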

Results

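Liver RNA from 12 Sprague-Dawley rats was measured on expression arrays, with 1 array per animal and 3 animals in each of 4 groups. The groups were a normal diet, a high-fat diet (HFD), the HFD with Qushi Huayu Decoction (QHD, a Chinese herbal medicine), and the HFD with a mixture of the plant compounds geniposide and chlorogenic acid (GC). The series addresses how QHD acts in the fatty liver that such a diet brings, and sets the decoction beside the mixture. The labels give QHD as 0.1 ml/kg by daily gavage for 4 weeks after 4 weeks of the HFD, and give no dose for GC, so the QHD and GC arms are compared as given and not at a matched dose. The titles give 4 weeks for every group, the HFD group included, while QHD and GC followed 4 weeks of the HFD. The full time of the HFD group on its diet is not given in the sources used here. Whether the time on the HFD differs between these groups is therefore not known. Every array held a signal for 31099 probe sets, of which 76 to 220 stood at 0. The median log2 signal was 6.62 to 6.87 on 11 arrays and 7.19 on the array labelled normal diet 3. The number of arrays limits the precision of every comparison.

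The array labelled normal diet 3 held little mRNA of hepatocyte genes and much mRNA of fat cell genes. Its median over 15 hepatocyte markers was log2 6.28, against 14.61 to 15.06 on the other 11 arrays, and its median over 9 adipocyte markers was 14.41, against 4.02 to 5.79. Adipoq, the fat cell hormone adiponectin, stood at log2 14.41 against a mean of 4.17 on the other arrays, and Plin1, a coat protein of fat droplets, at 14.28 against 4.67. Apoa1, the main protein of high-density lipoprotein, stood at 5.08 against 14.54, and Apob, the protein of very-low-density lipoprotein, at 4.99 against 15.13. Across the genes tested, which are not independent replicates, its signals correlated at 0.392 to 0.447 with those of the other arrays, which correlated at 0.929 to 0.981 with each other. Each comparison was therefore made over all 12 arrays and again over the 11 without this array. The genes are described from the 11 arrays, a fit chosen after this array's values were seen, in which the normal diet group has 2 animals. In the comparisons between HFD, QHD and GC this array enters through the spread that all groups share and through the choice of genes tested, 9485 over 12 arrays and 9459 over 11. With limma's array weights, which estimate each array's precision from the data, the 12 arrays gave 588 changed genes for HFD against normal, 261 for QHD against HFD, 434 for GC against HFD and 140 for QHD against GC, where equal weights gave 0 in each.

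**Figure D1:**
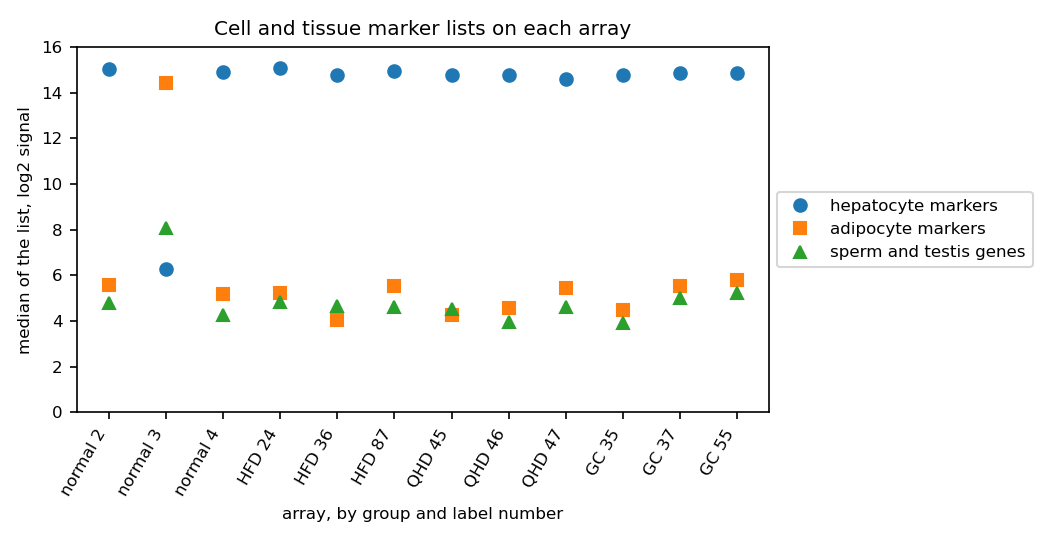
Median log2 signal (vertical axis) of 15 hepatocyte markers, 9 adipocyte markers and 25 sperm and testis genes on each of the 12 arrays (horizontal axis, by group and label number), 1 point per list and array. On the array labelled normal diet 3 the hepatocyte median is 6.28 and the adipocyte median 14.41, while on the other 11 the hepatocyte medians lie at 14.61 or above and the adipocyte medians at 5.79 or below.

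Among the other 11 arrays the 2 normal diet arrays stood apart on the first principal component of the tested genes, which held 38.0% of the variance, while the HFD, QHD and GC arrays overlapped. The normal diet arrays lay at -39.8 and -33.0 and the HFD arrays at -17.3, -8.13 and 16.2. The QHD arrays lay at 8.48 to 14.2 and the GC arrays at 8.09 to 23.0. On the second component, with 13.0% of the variance, the QHD arrays (8.56 to 22.3) did not overlap the HFD arrays (-17.2 to -2.88) or the GC arrays (-11.5 to -2.14). The labels name no batch.

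**Figure D2:**
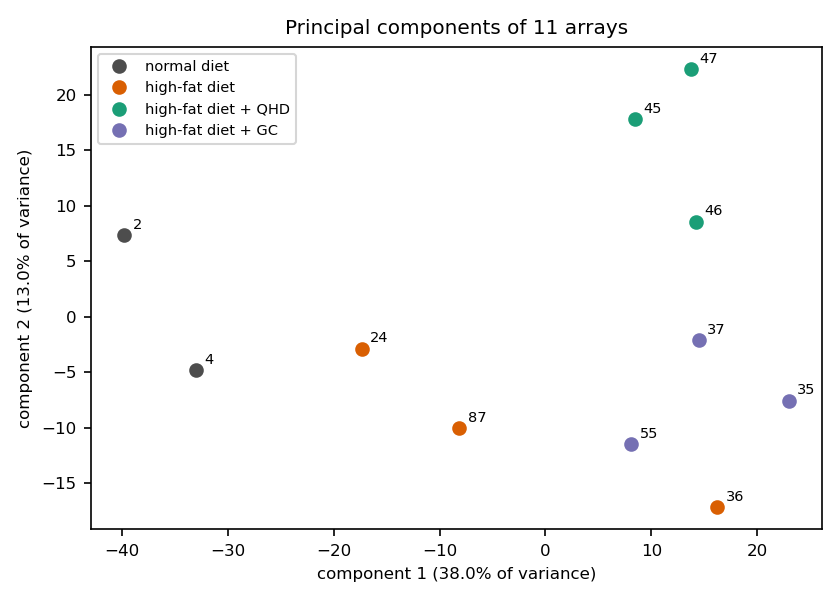
First 2 principal components of the log2 signals of the tested genes over 11 arrays, without the array labelled normal diet 3, with the share of variance on each axis (38.0% and 13.0%, scores in arbitrary units). Each point is 1 array coloured by group; the normal diet arrays lie at -39.8 and -33.0 on the first component and the treated arrays at 8.09 or above.

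The comparison of HFD with normal diet asks what the diet itself does to the liver. With the 11 arrays, mRNAs of cholesterol synthesis fell and mRNAs of class II antigen presentation rose on the HFD. Of 19 measured genes of cholesterol synthesis and uptake, 8 fell and none rose, and 13 fell with p adjusted over the list alone. Tm7sf2, a sterol reductase of cholesterol synthesis, went from log2 11.69 ± 0.12 (SD, n = 2) to 8.69 ± 0.35 (SD, n = 3), a fall of 7.97-fold (log2 change -3.0 ± 0.24, SE, adjusted p = 0.000496). Idi1, Msmo1 and Cyp51, enzymes of the same pathway, changed by -2.33 ± 0.24, -2.19 ± 0.18 and -1.98 ± 0.20 (SE), and Fdft1, the squalene synthase, by -1.24 ± 0.22. Insig1, which holds the sterol-sensing transcription factors in the endoplasmic reticulum and makes no sterol, changed by -1.31 ± 0.24 (adjusted p = 0.0448). Its call hung on single arrays: it was lost without HFD 36, HFD 87, QHD 45, QHD 46, any GC array or either normal diet array. The list was called lower by camera (adjusted p = 1.12e-22), and it was the only list of this comparison that stayed called with an estimated correlation (adjusted p = 0.0359 with an estimated correlation).

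Of 8 measured genes of MHC class II, 4 rose, and 7 rose with p adjusted over the list alone. Cd74, the invariant chain of class II molecules, rose by log2 1.76 ± 0.17 (SE, 3.38-fold, adjusted p = 0.00179, n = 3 against 2), and the class II chains RT1-Ba, RT1-Db1 and RT1-Da rose by 2.14 ± 0.28, 2.01 ± 0.27 and 1.83 ± 0.30. Marchf1, a ubiquitin ligase that acts on class II molecules, rose by 1.72 ± 0.25. Camera called the class II list higher (adjusted p = 6.03e-11; adjusted p = 0.122 with an estimated correlation). Markers of macrophages and Kupffer cells had a median log2 change of 0.86 over 17 genes, with 0 passing over all genes and 9 with p adjusted over the list alone, and camera called them higher (adjusted p = 1.06e-07; adjusted p = 0.311 with an estimated correlation). Of 27 inflammatory cytokines and NF-kB targets 1 rose, the adhesion molecule Vcam1 (1.47 ± 0.19), and 12 with p adjusted over the list alone; camera called the list higher (adjusted p = 4.09e-07; adjusted p = 0.311 with an estimated correlation). Ubd, a ubiquitin-like protein, rose by 2.22 ± 0.28 and the B cell gene Fcrla by 2.0 ± 0.33. The 5 markers of B and plasma cells, which carry class II molecules as well, had a median of 1.1, with 1 passing over all genes and 2 with p adjusted over the list alone, and were called higher by camera (adjusted p = 0.000545; adjusted p = 0.122 with an estimated correlation). Prc1, which acts in cell division, rose from log2 4.05 ± 0.38 (SD) to 7.33 ± 0.83. The first mean lies under 6.71, the level a gene's mean had to pass over the 12 arrays. With 32 added to the linear signals the rise was 2.01.

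**Figure D3:**
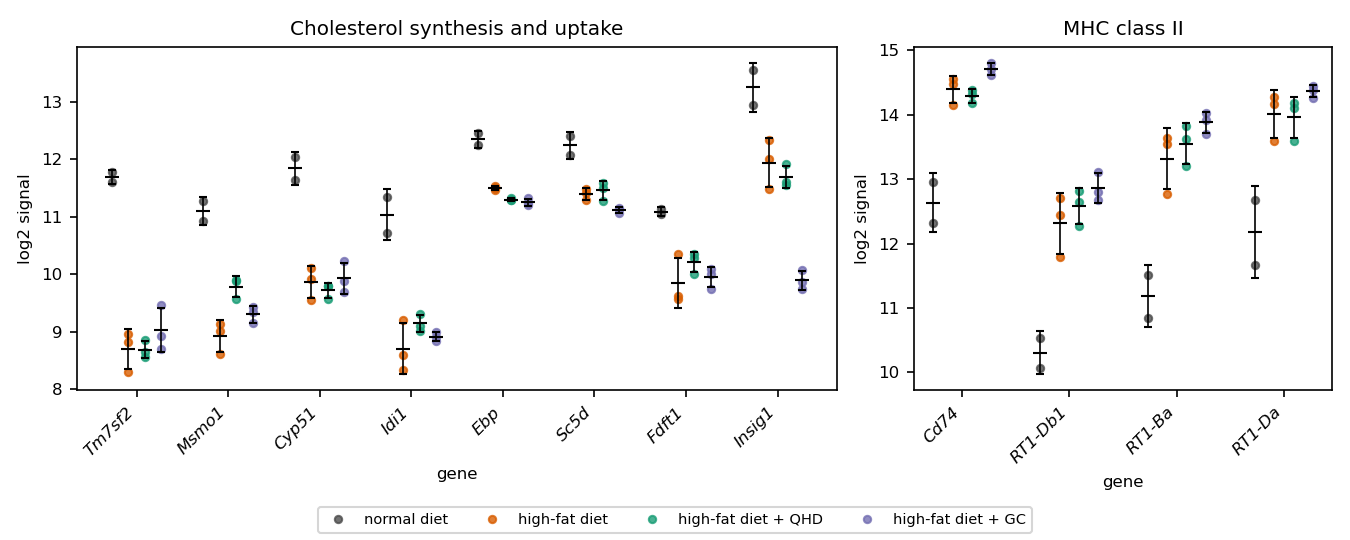
Log2 signal (vertical axis) of the 8 genes of cholesterol synthesis and uptake that fell on the HFD (left) and the 4 class II genes that rose (right), in each group over 11 arrays, without the array labelled normal diet 3. Points are arrays and the black marks are the mean ± SD; Tm7sf2 lies at 11.69 ± 0.12 on the normal diet and 8.69 ± 0.35 on the HFD, and Cd74 at 12.64 ± 0.46 and 14.39 ± 0.21.

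Single genes of other lists fell as well. Alas1, the first enzyme of heme synthesis, fell by 1.65 ± 0.26 (SE) and the peroxisomal gene Hsdl2 by 1.25 ± 0.18. Acss2, which makes acetyl-CoA from acetate, changed by -1.05 ± 0.15, Ugt2b1, a glucuronosyltransferase of drug metabolism, by -1.0 ± 0.18, and Gclm, a subunit of the enzyme that begins glutathione synthesis, by -0.87 ± 0.11. Genes of fatty acid oxidation and PPAR alpha targets had a median log2 change of -0.37 over 29 genes, with 0 passing over all genes or with p adjusted over the list alone, and camera called them lower (adjusted p = 4.84e-08; adjusted p = 0.311 with an estimated correlation). Of the fixed panel of fatty liver genes, none of the 15 measured passed. Srebf1, the transcription factor of lipid synthesis, had a log2 change of 1.57 ± 0.46 (adjusted p = 0.142), Scd, the stearoyl-CoA desaturase, 1.39 ± 0.64 (adjusted p = 0.36) and Fasn, the fatty acid synthase, -0.23 ± 0.52. Ccl2, which draws monocytes, had 2.55 ± 0.90 (adjusted p = 0.222).

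In all, limma called 50 of 9459 genes over the 11 arrays, 31 higher and 19 lower on the HFD, with 1364 at an unadjusted p under 0.05 where chance gives 473. Over all 12 arrays, the fit chosen before the data were examined, limma called 0 of 9485 genes, with 590 at an unadjusted p under 0.05 where chance gives 474, the smallest adjusted p being 0.114. In the authors' deposited table, 699 of 31099 probe sets had p under 0.05 for this comparison, where chance gives 1555, and 0 passed after Benjamini-Hochberg adjustment. Groups did not overlap in 28.3% of genes over the 11 arrays, where chance gives 20%. The count of 50 became 309 without HFD 24, 28 without HFD 87 and 12 without normal diet 2. Of the 23 named genes that passed, Cd74, Cyp51, Idi1, Inf2, Msmo1 and Tm7sf2 kept their call whichever of the 11 arrays was left out, and without normal diet 2 no other did. Of the 23, only Tm7sf2 kept its call under every other setting tried over the 11 arrays. Over the 12 arrays the signs of Alas1 (log2 change 0.01) and Ugt2b1 (1.72) turned. Camera called 20 of 32 lists over the 11 arrays and 23 over the 12, 8 in the same direction in both and 5 in opposite directions, and with an estimated correlation 1 over the 11 and 0 over the 12. The lists of fatty acid oxidation, bile acids, cytochrome P450 and amino acids were lower over the 11 and higher over the 12, and fibrosis genes the reverse. With array weights the 11 arrays gave 267 genes, with only the HFD and normal groups in the fit 1, and without moderation of the variances 4.

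QHD was compared with HFD to see what the decoction changed in livers on the diet. Glutathione synthesis and conjugation mRNAs were higher with QHD over the 11 arrays. Of 33 measured NRF2 and glutathione genes 7 rose and 0 fell, and 12 rose with p adjusted over the list alone. Gsta3, a glutathione transferase, went from log2 7.85 ± 0.17 to 11.60 ± 0.86 (SD, n = 3 in each), a rise of 13.4-fold (log2 change 3.75 ± 0.40, SE, adjusted p = 0.00347). Gstp1, another transferase, rose by 1.39 ± 0.19, and Gclm and Gclc, both subunits of the enzyme that begins glutathione synthesis, by 1.20 ± 0.10 and 0.75 ± 0.10. Gsr, which reduces oxidised glutathione, rose by 1.24 ± 0.22 and Akr7a3, an aldehyde reductase, by 2.56 ± 0.44. The list was called higher by camera (adjusted p = 1.49e-09; adjusted p = 0.273 with an estimated correlation) and moved upward by fry (adjusted p = 0.0112).

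Genes of other lists changed singly. Ugt2b1, which had fallen on the HFD, rose by log2 1.38 ± 0.16 (SE, 2.61-fold) and was the only one of 33 cytochrome P450 and drug metabolism genes to pass, with 8 rising with p adjusted over the list alone. Msmo1 of cholesterol synthesis rose by 0.86 ± 0.16 (adjusted p = 0.0468), 1 of 19 in its list. Gckr, the regulatory protein that holds glucokinase in the nucleus, fell by 1.94 ± 0.14 (3.85-fold, adjusted p = 0.000273). Kynu, an enzyme of tryptophan breakdown, fell by 2.11 ± 0.23, and Afmid, an enzyme of the same route, rose by 1.81 ± 0.28. Npas2, a transcription factor of the clock, fell from log2 9.30 ± 1.20 (SD, n = 3) to 4.21 ± 0.94. The latter lies under 6.71, the level a gene's mean had to pass over the 12 arrays, so the size of the fall is not exact. With 32 added to the linear signals the log2 change was -3.69. Gk, the glycerol kinase, changed by -1.04 ± 0.18 and Lipc, the hepatic lipase, by -0.59 ± 0.10. None of the 15 panel genes measured passed; Scd had -2.59 ± 0.57 (adjusted p = 0.0887) and Plin2, a coat protein of fat droplets, -0.82 ± 0.22 (adjusted p = 0.134), while another probe set of Plin2 had 0.0411. Camera called 12 of 32 lists, 5 higher and 7 lower, and none with an estimated correlation. The 4 lists called over the 12 arrays as well were NRF2 and glutathione, cell cycle, proteasome and stellate cell markers. The 25 cell cycle genes had a median log2 change of 0.50, with 24 of them positive, 0 passing over all genes and 1 rising with p adjusted over the list alone (adjusted p = 0.000438; adjusted p = 0.626 with an estimated correlation). Also called were 30 proteasome genes (median log2 change 0.14; adjusted p = 0.476 with an estimated correlation), 15 hepatocyte markers (-0.20, or -0.0684 with quantile normalization; adjusted p = 0.626 with an estimated correlation) and 10 stellate cell markers (-0.39; adjusted p = 0.476 with an estimated correlation). The called list of acute phase proteins had a median of -0.14, or -0.0316 with quantile normalization, a mean of 0.000925 and a test toward lower values (adjusted p = 0.0368; adjusted p = 0.626 with an estimated correlation).

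**Figure D4:**
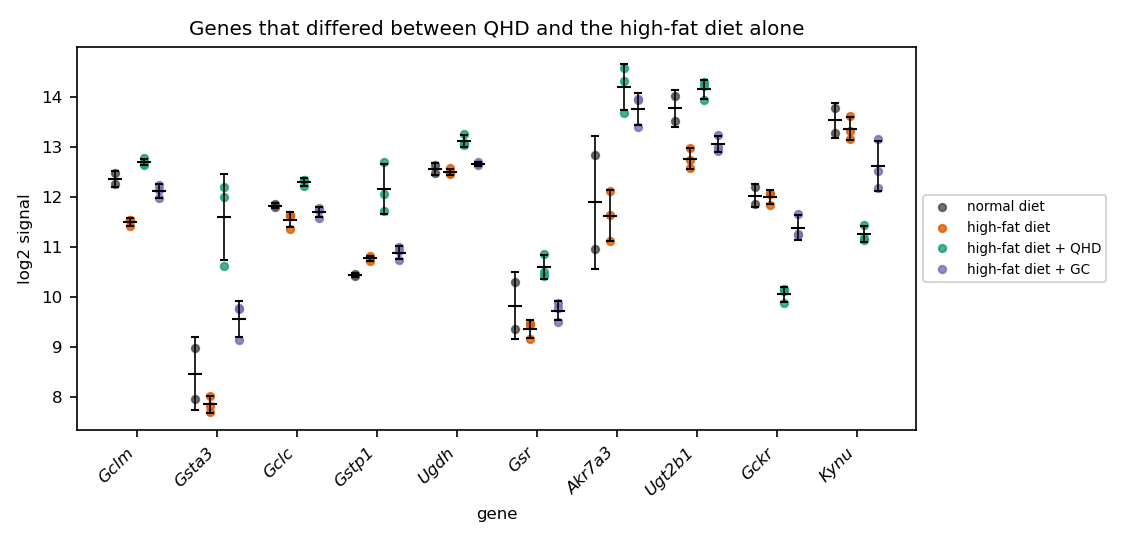
Log2 signal (vertical axis) of the 7 NRF2 and glutathione genes that rose with QHD and of Ugt2b1, Gckr and Kynu (horizontal axis), in each group over 11 arrays, without the array labelled normal diet 3. Points are arrays and the black marks are the mean ± SD; Gsta3 lies at 7.85 ± 0.17 on the HFD and 11.60 ± 0.86 with QHD, and Gckr at 12.00 ± 0.14 and 10.05 ± 0.15.

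Limma called 53 of 9459 genes over the 11 arrays, 30 higher and 23 lower with QHD, with 1205 at an unadjusted p under 0.05 where chance gives 473. Over all 12 arrays it called 0, with 348 at an unadjusted p under 0.05 and the smallest adjusted p at 0.0705; the 2 groups compared hold the same arrays in both fits. In the authors' deposited table, 1658 of 31099 probe sets had p under 0.05, where chance gives 1555, and 0 passed after adjustment. Groups did not overlap in 17.5% of genes, where chance gives 10%. The count of 53 became 162 without HFD 36, 18 without HFD 87, and 24 without QHD 45 and likewise without QHD 47. Of the 25 named genes that passed, Gckr, Gclc, Gclm, Gsta3, Gstp1, Kynu, Mcrip2, Mreg, Mtmr7 and Ugt2b1 kept their call whichever array was left out; 12 kept it without HFD 87, where the adjusted p of Npas2 was 0.0553. Of the 25, only Gckr, Gclm and Mcrip2 kept their call under every other setting tried over the 11 arrays. Over the 12 arrays camera called 4 lists, all of them called in the same direction over the 11, and 0 with an estimated correlation. With array weights the 11 arrays gave 434 genes, with only these groups in the fit 20, and without moderation 8.

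GC was compared with HFD to see what the mixture changed. Few genes passed over the 11 arrays. Insig1 had already been called lower on the HFD, a call that hung on single arrays. With GC it was lower again, from log2 11.94 ± 0.43 to 9.89 ± 0.16 (SD, n = 3 in each), a log2 change of -2.05 ± 0.22 (SE, 4.14-fold, adjusted p = 0.00701). It was the only one of 19 cholesterol synthesis and uptake genes to pass. Sall1, a zinc finger transcription factor, fell by 1.55 ± 0.17 (adjusted p = 0.00701), Col4a5, a chain of basement membrane collagen, by 1.42 ± 0.22 and Aadac, a deacetylase of drug and lipid metabolism, by 1.06 ± 0.16. Mtmr7, AKR1C3l1, Pkdcc and Rcan2 changed by -1.44, -1.38, -1.26 and -1.17. Atp6v1d, a subunit of the vacuolar proton pump, rose by 0.64 ± 0.09. None of the 15 panel genes measured passed; Scd had -2.37 ± 0.57 (adjusted p = 0.314) and Plin2 -0.65 ± 0.22 (adjusted p = 0.434), while another probe set of Plin2 had 0.0392.

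Camera called lists none of whose members passed singly, and each of these calls was lost with an estimated correlation. Genes of fatty acid oxidation and PPAR alpha targets had a median log2 change of -0.29 over 29 genes, 2 falling with p adjusted over the list alone, and amino acid and urea cycle genes one of -0.34 over 34 genes, 6 falling with p adjusted over the list alone. Camera called both lower (adjusted p = 1.13e-10 for each; adjusted p = 0.469 with an estimated correlation for each). Glucose metabolism and insulin signalling genes had a median of -0.24 and were called lower (adjusted p = 0.000535; adjusted p = 0.469 with an estimated correlation). Inflammatory cytokines and NF-kB targets had a median of 0.40 and were called higher (adjusted p = 0.00194; adjusted p = 0.603 with an estimated correlation). Immune lists were called higher too: 17 macrophage and Kupffer cell markers (median 0.23, adjusted p = 0.0318; adjusted p = 0.658 with an estimated correlation), 8 MHC class II genes (0.43, adjusted p = 0.00891; adjusted p = 0.603 with an estimated correlation) and 13 T and NK cell markers (0.28, adjusted p = 0.00643; adjusted p = 0.603 with an estimated correlation). For the class II gene RT1-Ba, another probe set past the filter had -1.38, where the one used had 0.57. Another of RT1-Db1 had 0.71, in the direction of the one used (0.55). Stellate cell markers had a median of -0.35 over 10 genes (adjusted p = 0.00194; adjusted p = 0.469 with an estimated correlation). Camera called 19 of 32 lists, 7 higher and 12 lower, none of them with an estimated correlation, and fry called 0. The count of 19 became 7 without HFD 24 and 12 without GC 35.

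Limma called 9 of 9459 genes over the 11 arrays, 1 higher and 8 lower with GC, with 829 at an unadjusted p under 0.05 where chance gives 473. Over all 12 arrays it called 0, with 224 at an unadjusted p under 0.05 and the smallest adjusted p at 0.552. In the authors' deposited table, 1214 of 31099 probe sets had p under 0.05, where chance gives 1555, and 0 passed after adjustment. Groups did not overlap in 13.5% of genes, where chance gives 10%. The count of 9 rested on single arrays. It became 126 without HFD 36, 0 without HFD 87, 3 without HFD 24, 1 without GC 35 and 2 without GC 37, and leaving out arrays of the groups not compared gave 2 without normal diet 2, normal diet 4, QHD 46 or QHD 47 and 3 without QHD 45. None of the 9 named genes kept its call in every such fit; Sall1 lost it only without HFD 87 (adjusted p = 0.0714), and Insig1 without HFD 87 or GC 35 (adjusted p up to 0.0808). With array weights the 11 arrays gave 659 genes, without the trend and the robust option 2, and without moderation or with only these groups in the fit 0.

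QHD was set directly against GC, which tests whether the decoction and the mixture differ. Over the 11 arrays, 3 of 33 NRF2 and glutathione genes were higher with QHD than with GC and 0 lower, and 7 were higher with p adjusted over the list alone. Gstp1 was at log2 12.16 ± 0.49 with QHD and 10.89 ± 0.13 with GC (SD, n = 3 in each), a difference of 1.27 ± 0.19 (SE, 2.42-fold, adjusted p = 0.0253), and Gclc and Gclm were higher by 0.60 ± 0.10 and 0.58 ± 0.10. These calls hung on single arrays: Gstp1 lost its own without any of 4 arrays, Gclc without any of 9 and Gclm without any of 10 of the 11 (adjusted p up to 0.121, 0.211 and 0.226). Camera called the list higher (adjusted p = 1.15e-08; adjusted p = 0.189 with an estimated correlation). Ugt2b1 was higher by 1.09 ± 0.16, 1 of 33 cytochrome P450 and drug metabolism genes, with 6 higher with p adjusted over the list alone, and camera called that list higher (adjusted p = 1.22e-06; adjusted p = 0.675 with an estimated correlation). Insig1 was higher by 1.80 ± 0.22 (adjusted p = 0.00804) and Abcc3, an exporter of bile acid and drug conjugates, by 1.60 ± 0.27. Gckr had a log2 difference of -1.34 ± 0.14 (adjusted p = 0.00344) and Kynu one of -1.36 ± 0.23.

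Other named genes differed as well. Npas2 was lower with QHD (adjusted p = 0.0491), but its QHD mean of log2 4.21 lay under 6.71, the level a gene's mean had to pass to be tested, and with 32 added to the linear signals it no longer passed (log2 change -2.57, adjusted p = 0.0878). Cry1, a repressor of the clock, had 1.54 ± 0.26 (SE). Lama3, a laminin chain, was higher with QHD by 2.02 ± 0.25 and Rcan2, a regulator of calcineurin, by 1.51 ± 0.16. Xiap, an inhibitor of apoptosis, had -1.35 ± 0.19 and Oaf -1.12 ± 0.12. Interferon responsive genes had a median log2 difference of -0.46 over 38 genes with 0 passing, and were called lower with QHD by camera (adjusted p = 0.00112; adjusted p = 0.741 with an estimated correlation). Macrophage and Kupffer cell markers had a median of -0.24 over 17 genes (adjusted p = 0.0189; adjusted p = 0.741 with an estimated correlation). For the genes that did not pass, intervals were not computed, and the absence of a call does not show that both treatments act alike.

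Limma called 26 of 9459 genes over the 11 arrays, 18 higher and 8 lower with QHD, with 944 at an unadjusted p under 0.05 where chance gives 473. Over all 12 arrays it called 0, with 273 at an unadjusted p under 0.05 and the smallest adjusted p at 0.612; the authors' deposited table holds no such comparison. Groups did not overlap in 18.5% of genes, where chance gives 10%. The count of 26 became 59 without HFD 36, 8, 7 and 6 without GC 35, GC 37 and GC 55, and 11, 10 and 8 without QHD 45, QHD 46 and QHD 47. Of the 20 named genes that passed, Gckr, Lama3, Mcrip2, Oaf and Rcan2 kept their call in each of these fits. Only Mcrip2 kept it under every other setting tried over the 11 arrays. Camera called 14 of 32 lists, 10 higher and 4 lower, and 9 over the 12 arrays, which were all among the 14 in the same direction. With an estimated correlation it called 0 over either set, and fry called 0 as well. With array weights the 11 arrays gave 185 genes, with only these groups in the fit 70, without the trend and the robust option 10, and without moderation 3.

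The genes of the diet were followed into the treated livers. Of the 50 genes that the HFD changed over the 11 arrays, limma called 3 back toward normal with QHD, Gclm, Msmo1 and Ugt2b1, all of which had fallen on the HFD and were higher with QHD; independent calls would share 0.0603 genes in this direction. These comparisons share the HFD arrays. In 100 simulations of unchanged groups with each gene's own spread, as many genes were taken by smallest p, whether or not they passed. Of these, 2 to 16 were shared with opposite directions (mean 10.1). The simulated groups held no change by the diet, so the ranges from this simulation do not test whether a diet change was reversed. Its genes were drawn independently, so the ranges may also be too narrow for genes that move together. The count of 3 is thus not shown to exceed what shared arrays can give. Gclm changed by -0.87 ± 0.11 (SE) on the HFD and by 1.20 ± 0.10 with QHD, Msmo1 by -2.19 ± 0.18 and 0.86 ± 0.16, and Ugt2b1 by -1.0 ± 0.18 and 1.38 ± 0.16. GC called back 0 of the 50 by limma, where the same simulation gave 1 to 8 (mean 3.97). Insig1 was called lower on the HFD and lower again with GC, where independent calls would share 0.0161 genes and the simulation 0. Both of its calls were lost when some single arrays were left out. At an unadjusted p no count was made; 28 of the 50 had the opposite sign with QHD and 16 with GC, where unchanged groups sharing these arrays gave 32 to 47 and 31 to 47 in the simulation. Against normal, 46 with QHD and 48 with GC were called in the direction of the diet, where as many genes taken by smallest p gave 32 to 46 and 33 to 47. Over all 12 arrays both counts were 0, since no gene was called for the diet, and with array weights they were 24 for QHD and 22 for GC. Over the 11 arrays the count of 3 became 8 without HFD 36, 6 without HFD 24, 5 without normal diet 4 and 1 without normal diet 2 or QHD 45, and the count of 0 for GC became 4 without HFD 36. Both counts use the HFD arrays in both comparisons, and 3 arrays cannot be divided into sets of 2.

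Across 9485 genes, which are not independent replicates, the log2 changes of QHD against HFD and GC against HFD correlated at 0.560 over the 12 arrays (jackknife SE 0.175). Unchanged groups that share the 3 HFD arrays gave 0.599 in simulation with each gene's own spread and 0.502 with the pooled spread. The covariance was 0.0544, against a simulated 0.0386 with each gene's own spread and 0.150 with the pooled spread, which the array labelled normal diet 3 widens; over the 11 arrays it was 0.0540 against 0.0376 and 0.0296. The correlation was 0.709 without HFD 36. Over the 11 arrays 2 genes fell in both treated groups, Mtmr7 and AKR1C3l1, but both lists use the same HFD arrays, and unchanged groups sharing them gave 1 to 7 (mean 4.22) in the simulation.

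Both treated groups were last compared with the normal diet. Over the 11 arrays limma called 706 genes for QHD, 451 higher and 255 lower, and 909 for GC, 586 higher and 323 lower. Lcn2, which binds iron carriers of bacteria, rose by log2 4.99 ± 0.67 (SE, n = 3 against 2) for QHD and 3.81 ± 0.67 for GC. Itgam, an integrin of myeloid cells, Saa3, an acute phase protein, and Ccl2 also rose in both, from normal diet means of log2 2.93, 3.21 and 6.06. These lie under 6.71, the level a gene's mean had to pass over the 12 arrays, so the sizes are not exact. With 32 added to the linear signals the sizes were 2.73 and 2.90 for Itgam, 3.13 and 3.06 for Saa3, and 3.52 and 3.14 for Ccl2. Prlr, the prolactin receptor, fell in both to means of 6.60 and 6.38, also under that level (log2 changes of -3.11 and -3.24 with 32 added). Tm7sf2 changed by -3.0 ± 0.24 and -2.66 ± 0.24. Insig1 changed by -3.36 ± 0.24 with GC. Over all 12 arrays limma called 4 genes for QHD, which were Lcn2 (5.05 ± 0.61), Marchf1 (1.89 ± 0.24), Tmem86a (1.09 ± 0.12) and Npas2, which fell to a mean of 4.21, under that level, and 65 for GC, 51 higher and 14 lower, among them Cxcl9, a chemokine of T cells (3.59 ± 0.63), Il1b, an inflammatory cytokine (3.01 ± 0.51), and Insig1 (-2.98 ± 0.34). All 4 and all 65 were also called over the 11. At an unadjusted p under 0.05 the 12 arrays gave 1183 and 1187 genes, where chance gives 474. In the authors' deposited table, which includes the array labelled normal diet 3, 1300 and 1267 of 31099 probe sets had p under 0.05. Chance gives 1555, and 0 passed after adjustment.

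These counts moved with single arrays. Over the 11, the count of 706 became 136 without normal diet 2, 135 without normal diet 4, 397, 250 and 242 without QHD 45, QHD 46 and QHD 47, and 457 without GC 37, and the count of 909 became 164 without normal diet 2, 362 without normal diet 4, 399 without GC 35 and 438 without GC 37. Of the named genes that passed, 18 of 74 for QHD and 16 of 85 for GC kept their call whichever array was left out. Abcb4, Acss2, Cd74, Ebp, Prc1, RT1-Ba, RT1-Db1, Tm7sf2 and Vcam1 did so in both, and among the others were Lcn2 and Npas2 for QHD and Prlr and Insig1 for GC. Of these named here, all but RT1-Ba also kept the call under every other setting tried over the 11 arrays. Itgam lost its call without normal diet 2 in both and without normal diet 4 for QHD (adjusted p up to 0.111). Saa3 lost it without normal diet 2 or normal diet 4 in both (adjusted p up to 0.0816), Prlr without normal diet 4 for QHD (adjusted p = 0.0663), Lcn2 without normal diet 2 for GC (adjusted p = 0.0712) and Ccl2 without any of 5 arrays in each (adjusted p up to 0.148), among them both normal diet arrays. Over the 12 arrays the count of 4 became 0 without any array of the GC, QHD or normal groups other than normal diet 3 and without HFD 87, and 15 without HFD 36; the count of 65 became 0 to 10 without any of these or HFD 87, and 102 and 115 without HFD 24 and HFD 36. Centring each array on its median gave 312 genes higher and 384 lower for QHD over the 11 arrays and 446 higher and 505 lower for GC, and shifted the median change of all genes for GC from 0.05 to -0.05.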

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

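The tests of fat, of hepatocyte RNA and of RNA quality below were chosen after seeing the values of the array labelled normal diet 3, and only the prediction for the male tract was written before its test.

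The array labelled normal diet 3 lay far from the other 11 in marker lists of fat cells and of sperm and testis, which none of the list tests uses. Its adipocyte markers had a median log2 signal of 14.41, and over the 9 genes the median difference from the other arrays was 7.06, with 8 higher by over 2 log2 units, as RNA of fat tissue in place of liver would give. Hepatocyte RNA kept with a small admixture is excluded by a median difference of -8.52 over 15 hepatocyte markers, 13 of them lower by over 2. The 3 prime minus 5 prime log2 difference of Gapdh was 0.35, inside the range of 0.33 to 0.63 of the other arrays. That of Actb was 2.55, inside 1.98 to 2.63. These values gave no sign of degraded RNA, but they do not measure other faults of an array, so a failed array is not excluded by them. The 25 sperm and testis genes were higher by a median of 3.13, 16 of them by over 2, as tissue of the male tract beside the fat would give; Prm1 of sperm chromatin stood at 14.31 against 2.64, but this gene, Tnp1, Tnp2 and Odf1 had been seen before the list was chosen.

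Lists of other tissues moved less on this array. The median difference was 2.01 for endothelial markers, 1.04 for erythroid, 0.58 for skeletal muscle, 0.15 for cholangiocyte, -0.01 for pancreatic acinar and -0.17 for neutrophil markers. Macrophage and Kupffer cell markers had -0.91, B and plasma cell markers -1.28 and T and NK cell markers -0.47. Stellate cell markers had 0.45, with 5 higher and 4 lower by over 2. The 4 epididymis genes had 1.46, 2 of them higher by over 2 and 0 lower. The array labelled normal diet 3 thus leaves 2 liver arrays on the normal diet, and which animal or tissue it came from is not given in the sources used here.

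Probe sets without a single gene name were tested apart from the genes, 3258 of them over the 11 arrays. Past the threshold lay 9 for HFD vs normal (5 higher, 4 lower), 12 for QHD vs HFD (3 higher, 9 lower), 3 for GC vs HFD (1 higher, 2 lower) and 4 for QHD vs GC (1 higher, 3 lower). They were not named, since no genome of the rat came with the data.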

How the results depend on the processing

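Leaving out the array labelled normal diet 3 moved all 6 gene counts by over 1.5 times. Of the log2 changes of named genes under the other settings, counted once per gene, comparison and setting, 5930 kept their direction and their side of the threshold, 1270 kept the direction but no longer passed, 7 came to pass and 110 took the opposite sign. The cause of a moved count was not tested, except that a looser threshold on the same p values can only add genes. Over the 11 arrays quantile normalization moved only the called-back count for GC by over 1.5 times, and centring moved none. Centring gave 31 higher and 29 lower genes for HFD vs normal over the 11 arrays, in place of 31 and 19, 312 and 384 for QHD vs normal in place of 451 and 255, and 446 and 505 for GC vs normal in place of 586 and 323. Over the 12 arrays QHD vs normal had 3 higher and 1 lower, 4 and 3 with quantile normalization, 3 and 2 with centring and 3 and 0 with 32 added before the log. The other deposited table held the same values and moved nothing. The fit without moderation and the fold threshold give no list test, and the thresholds do not apply to the correlation. No paired analysis was possible because the labels share no animal numbers between groups. Leaving out either remaining normal diet array leaves 1 normal animal, which is then assumed to vary like the other groups. The settings over the 11 arrays were chosen after seeing the data. Genes with a mean log2 signal under the median of all probe sets, 6.71 over the 12 arrays, were not tested, so the signal over background limits what could be called.

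Over the 12 arrays these settings moved a count by over 1.5 times, counted in genes unless lists are named. Arrays centred on their median gave 2 for HFD vs normal (from 0). No moderation of the variances gave 1 for HFD vs normal (from 0) and 1 for GC vs normal (from 65). Array weights gave 588 for HFD vs normal (from 0), 261 for QHD vs HFD (from 0), 434 for GC vs HFD (from 0), 140 for QHD vs GC (from 0), 1727 for QHD vs normal (from 4), 2357 for GC vs normal (from 65), 15 for lists in HFD vs normal (from 23), 7 for lists in QHD vs HFD (from 4), 24 for called back by QHD (from 0) and 22 for called back by GC (from 0). A stricter filter gave 1 for QHD vs HFD (from 0), 8 for QHD vs normal (from 4) and 2 for lists in QHD vs HFD (from 4). Only the groups compared in the fit gave 20 for QHD vs HFD (from 0), 70 for QHD vs GC (from 0), 1 for QHD vs normal (from 4), 1 for GC vs normal (from 65), 11 for lists in QHD vs HFD (from 4) and 15 for lists in QHD vs GC (from 9). Adjusted p under 0.1 gave 2 for QHD vs HFD (from 0), 20 for QHD vs normal (from 4) and 185 for GC vs normal (from 65). Quantile normalization gave 7 for QHD vs normal (from 4). No expression filter gave 3 for GC vs normal (from 65). Camera's estimated correlation gave 0 for lists in HFD vs normal (from 23), 0 for lists in QHD vs HFD (from 4), 0 for lists in GC vs HFD (from 13) and 0 for lists in QHD vs GC (from 9). Fry in 1 direction gave 1 for lists in HFD vs normal (from 23), 0 for lists in QHD vs HFD (from 4), 0 for lists in GC vs HFD (from 13) and 0 for lists in QHD vs GC (from 9).

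With each array left out in turn the gene counts over the 12 arrays were 0 to 9 for GC vs HFD, 0 to 909 for GC vs normal, 0 to 50 for HFD vs normal, 0 to 26 for QHD vs GC, 0 to 53 for QHD vs HFD and 0 to 706 for QHD vs normal. The list counts were 2 to 19 for lists in GC vs HFD, 20 to 24 for lists in HFD vs normal, 2 to 14 for lists in QHD vs GC and 4 to 12 for lists in QHD vs HFD. The called-back counts were 0 to 0 for called back by GC and 0 to 3 for called back by QHD. The correlation was 0.492 to 0.709.

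Over the 11 arrays the same settings were tried. No moderation of the variances gave 4 for HFD vs normal (from 50), 8 for QHD vs HFD (from 53), 0 for GC vs HFD (from 9), 3 for QHD vs GC (from 26), 162 for QHD vs normal (from 706), 255 for GC vs normal (from 909) and 0 for called back by QHD (from 3). Only the groups compared in the fit gave 1 for HFD vs normal (from 50), 20 for QHD vs HFD (from 53), 0 for GC vs HFD (from 9), 70 for QHD vs GC (from 26) and 0 for called back by QHD (from 3). Array weights gave 267 for HFD vs normal (from 50), 434 for QHD vs HFD (from 53), 659 for GC vs HFD (from 9), 185 for QHD vs GC (from 26), 1458 for GC vs normal (from 909), 16 for called back by QHD (from 3) and 9 for called back by GC (from 0). Adjusted p under 0.1 gave 256 for HFD vs normal (from 50), 133 for QHD vs HFD (from 53), 43 for QHD vs GC (from 26), 1346 for QHD vs normal (from 706), 1585 for GC vs normal (from 909), 10 for called back by QHD (from 3) and 2 for called back by GC (from 0). No trend and no robust step gave 2 for GC vs HFD (from 9), 10 for QHD vs GC (from 26) and 1 for called back by QHD (from 3). Camera's estimated correlation gave 1 for lists in HFD vs normal (from 20), 0 for lists in QHD vs HFD (from 12), 0 for lists in GC vs HFD (from 19) and 0 for lists in QHD vs GC (from 14). Fry in 1 direction gave 4 for lists in HFD vs normal (from 20), 2 for lists in QHD vs HFD (from 12), 0 for lists in GC vs HFD (from 19) and 0 for lists in QHD vs GC (from 14). Quantile normalization gave 1 for called back by GC (from 0). A stricter filter gave 1 for called back by GC (from 0).

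With each array left out in turn the gene counts over the 11 arrays were 0 to 126 for GC vs HFD, 164 to 1271 for GC vs normal, 12 to 309 for HFD vs normal, 6 to 59 for QHD vs GC, 18 to 162 for QHD vs HFD and 135 to 1042 for QHD vs normal. The list counts were 7 to 21 for lists in GC vs HFD, 14 to 24 for lists in HFD vs normal, 10 to 16 for lists in QHD vs GC and 9 to 15 for lists in QHD vs HFD. The called-back counts were 0 to 4 for called back by GC and 1 to 8 for called back by QHD. The correlation was 0.496 to 0.708.

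The named genes whose log2 change took the opposite sign are given with the value under that setting, against the fit of 11 arrays. With all 12 arrays HFD vs normal had Alas1 0.0122, Ugt2b1 1.72, Acaca -0.81, Plin2 0.49, Cidec -0.84, Apob 3.36, Mttp 2.18, Pck1 0.30 and Col1a1 -1.28. With quantile normalization HFD vs normal had Plin2 0.00594. With the mean of a gene's probe sets HFD vs normal had Plin2 0.46 and Apob 0.089. With array weights HFD vs normal had Plin2 0.12. With quantile normalization QHD vs HFD had Apob 0.0209 and Pck1 0.0157. With array weights QHD vs HFD had Mttp -0.000352. With array weights GC vs HFD had Fasn 0.0644, Mttp -0.0935 and Pck1 -0.0366. With arrays centred on their median GC vs HFD had Mttp -0.00514 and Pck1 -0.027. With array weights QHD vs GC had Plin2 0.0929. With the mean of a gene's probe sets QHD vs GC had Apob -0.0919. With all 12 arrays QHD vs normal had Serpina7 1.33, Kynu 0.75, Apcs 2.0, Crp 2.33, Cth 2.03, Cbs 0.74, Lipc 2.90, Apoa5 2.31, Apom 2.06, Abcb4 0.13, Abcb11 1.97, Amacr 1.29, Slc10a1 2.99, Ebp 0.057, Fads2 0.73, Cyp4a3 1.98 and Hadh 0.0339. With all 12 arrays GC vs normal had Apoa4 0.73, Crp 2.22, Apcs 2.22, Aass 1.39, Cbs 0.77, Gls2 1.03, Cth 2.20, Apoa5 2.19, Lipc 3.29, Apom 2.04, Abcb4 0.31, Abcb11 1.84, Slc10a1 2.82, Slc27a5 2.38, Ebp 0.0113, Cyp3a9 1.59, Cyp2d3 2.38, Cyp2a1 2.09, Fads2 0.60, Elovl2 1.07, Cyp4a3 1.84, Ehhadh 0.98, Sult2a6 2.43, Igfbp1 1.34 and Ppp1r3b 0.0585.

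With single arrays left out, the lowest and highest log2 changes spanned 0 for some named genes, none of which had passed. For GC vs HFD they were -0.46 to 0.16 for Acaca, -0.73 to 0.31 for Fasn, -0.0796 to 0.0937 for Mttp, -0.0931 to 0.0804 for Pck1 and -0.37 to 0.66 for Srebf1. For HFD vs normal they were -0.00296 to 0.61 for Acaca, -0.15 to 0.039 for Apob, -0.0638 to 0.19 for Cidec, -0.37 to 0.58 for Cpt1a, -0.65 to 1.86 for Cyp7a1, -0.90 to 0.15 for Fasn and -0.30 to 0.22 for Plin2. For QHD vs HFD they were -0.22 to 0.39 for Acaca, -0.0733 to 0.18 for Cidec, -0.63 to 0.0319 for Col1a1, -0.42 to 0.0293 for Cpt1a, -0.27 to 0.77 for Fasn, -0.44 to 0.60 for Srebf1 and -0.33 to 1.22 for Tnf. For QHD vs GC they were -0.0421 to 0.0586 for Apob, -0.27 to 1.1 for Ccl2, -0.21 to 0.51 for Col1a1, -0.00626 to 0.25 for Cpt1a, -0.0256 to 0.17 for Mttp, -0.66 to 0.28 for Scd and -0.20 to 0.13 for Srebf1.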

Other observations

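The gene lists of treated against normal livers and the tests below over the 11 arrays were chosen after seeing the data, while the predictions for time on the diet, for the spread of the HFD arrays and for the splits were written before their tests, and the simulation of unchanged groups came after.

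Cholesterol synthesis genes were lower and class II genes higher in both treated groups when they were set against the normal diet. These comparisons share the 2 normal diet arrays with HFD vs normal, so they are not separate evidence that the change of the diet persisted. Of 19 genes of cholesterol synthesis and uptake 10 were lower with QHD and 12 with GC, 13 in each with p adjusted over the list alone (adjusted p = 0.141 and adjusted p = 0.0964 with an estimated correlation). Of 8 class II genes 7 were higher in each, and 7 in each with p adjusted over the list alone (adjusted p = 0.328 and adjusted p = 0.236 with an estimated correlation). Of 27 inflammatory genes 7 were higher with QHD and 14 with GC, 16 and 19 with p adjusted over the list alone (adjusted p = 0.351 and adjusted p = 0.286 with an estimated correlation). Of 17 macrophage and Kupffer cell markers 5 and 9 were higher, 10 and 14 with p adjusted over the list alone (adjusted p = 0.384 and adjusted p = 0.286 with an estimated correlation).

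Other lists gave different counts for QHD and GC against normal, and these counts are no test of a difference between QHD and GC. NRF2 and glutathione genes were higher than normal with QHD, 11 of 33 (adjusted p = 0.000161 by camera; adjusted p = 0.328 with an estimated correlation), and 2 of 33 with GC, where the list was not called (adjusted p = 0.744). Of 25 cell cycle genes 7 were higher with QHD and 1 with GC, 20 and 10 with p adjusted over the list alone (adjusted p = 0.338 and adjusted p = 0.365 with an estimated correlation). Genes of fatty acid oxidation and PPAR alpha targets were lower, 4 of 29 with QHD and 11 with GC, and 7 and 23 with p adjusted over the list alone (adjusted p = 0.338 and adjusted p = 0.257 with an estimated correlation). The bile salt exporter Abcb11 had -1.02 with QHD and -1.16 with GC, and over the 12 arrays 1.97 and 1.84, which the array labelled normal diet 3 turned. Camera called 23 lists in each comparison, and none with an estimated correlation. The median change of cytochrome P450 genes with QHD was -0.14, and 0.01 with quantile normalization, and that of oxidative phosphorylation genes with GC was -0.07, and 0.03 with quantile normalization.

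Late-day and late-night clock genes had medians of opposite sign with QHD against HFD, though HFD 24 lay inside the range of each treated group and the circadian list was not called (adjusted p = 0.208 for QHD and 0.858 for GC over the 11 arrays). With QHD the median log2 change was 1.45 for 8 late-day genes and -0.58 for 4 late-night genes, a difference of 2.03. That difference of medians was 1.42 for GC vs HFD, 0.04 for QHD vs GC, and 1.86 and 2.05 for QHD and GC against normal. It was thus not particular to QHD, but single clock genes differed between the treated groups. Nr1d1 lay at 6.25 to 7.36 on the QHD arrays and 9.12 to 9.90 on the GC arrays, and Npas2 was lower with QHD too. Per2 lay at 10.66 to 10.75 and 8.86 to 9.90, and Per1, Cry1 and Usp2 were higher with QHD too, while Dbp overlapped. A scaling difference between the arrays is excluded by the -0.58, since 1 factor per array would move both sets alike. Different hours of tissue collection may have produced the difference of 2.03 and cannot be told apart from effects of the treatments, since the labels give a cycle of 12 h of light and 12 h of dark and no hours. Late-day minus late-night signal was -1.46 and -1.22 on the normal diet arrays, 0.63 to 1.15 on the QHD arrays, -0.64 to 1.71 on the GC arrays, and 1.06 on HFD 24 against -2.56 and -1.73 on the other HFD arrays.

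By group means, treated livers lay further from normal than untreated HFD livers, but the HFD arrays were uneven. On the first principal component HFD 36 lay at 16.2, within the range of the treated arrays, 8.09 to 23.0. HFD 24 and HFD 87 lay at -17.3 and -8.13. The median size of the log2 change from normal was 0.166 for HFD, 0.226 for QHD and 0.224 for GC. The HFD arrays had a median SD of 0.196, 1.22 times the largest of the other groups, under the 1.5 times set for a larger spread as the source. Random spread alone would raise the size of the change and not lower it. This test does not reach differences between the HFD animals in how far they moved, so these are not excluded. Of 450 genes called against normal in both treated groups, 99.6% lay the same way in HFD vs normal. All 3 comparisons share the 2 normal diet arrays, and unchanged groups with as many genes taken by smallest p gave 96.4% to 99.8%, so this share holds no sign of a longer time on the HFD and does not exclude it; the titles give 4 weeks for the HFD group, and QHD and GC had 4 weeks of the HFD before their 4 weeks of treatment.

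The 6 arrays of a comparison can be grouped in only 10 ways, too few for a share under 0.05. Over the 12 arrays the real grouping gave 0 genes for HFD vs normal, QHD vs HFD, GC vs HFD and QHD vs GC, with 0 as the highest other, 4 for QHD vs normal with 1, and 65 for GC vs normal with 1. The lists numbered 23 with 23 as the highest other for HFD vs normal, 4 with 11 for QHD vs HFD, 13 with 13 for GC vs HFD and 9 with 10 for QHD vs GC. With the 11 arrays the genes were 53 with 1 for QHD vs HFD, 9 with 1 for GC vs HFD and 26 with 1 for QHD vs GC, and the lists 12 with 21, 19 with 18 and 14 with 15. Genes called back were 3 with 1 for QHD over the 11 arrays, and 0 with 0 for GC and for both over the 12. The correlation of QHD and GC effects, 0.560, was reached in 39 of 100 regroupings of the 9 arrays, the real one included, with 0.775 as the highest other and 0.514 as their median, so other groupings of these arrays give it as well.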
